A study of Homo sapiens with 4 samples.

How the data were processed

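RNA was sequenced from 4 samples of LCC9 cells, a tamoxifen-resistant breast cancer line that the labels describe as positive for wild-type estrogen receptor alpha. The cells were kept in medium without phenol red and with 5% charcoal-stripped serum, which holds little estrogen, and received vehicle (DMSO, 2 samples) or the compound A7 (2 samples) for 24 h, per the labels' protocols. Total RNA was made into cDNA with a SMARTer PCR kit, the cDNA was sheared, and adapters were ligated and amplified, per the labels' protocols. No step that marks the strand is named there, so reads of overlapping genes on opposite strands cannot be told apart. The labels do not say that the 2 samples of a group came from separate cultures, so p-values measure the spread between these samples only, which may be technical.

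The authors deposited 1 table per library with a gene symbol and its FPKM (fragments mapped to a gene, divided by transcript length and by the mapped fragments of the library), per the file headers. CASAVA 1.8.2, TopHat (version not given), Cufflinks 2.2.1 and genome build GRCh37 are listed in the submitters' processing notes, with no role or order. The gene annotation, the treatment of reads that map to several places and any further scaling between libraries are not given in the sources used here. Each table had 23619 lines in the same order, and 1 table had 2 empty columns. On 14 lines the symbol was a whole number (12 distinct numbers), as a spreadsheet writes a date, and named no gene. These lines held at most 0.00539% of a library's summed FPKM and were left out, which left 23605 symbols. Values far below 1e-03 occur and were kept as listed. Symbols are given as in the tables. The tables hold no positions, and the annotation at hand (GENCODE 29) is of another build, so no coordinates are given, and it was used only for transcript lengths, GC content and sequence copies.

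FPKM are not counts, so no count model was fitted. Each library was divided by its median ratio to the geometric mean of the 4 libraries, over genes with a mean FPKM of 1 or more and above 0 in every library. The factors were 1.002 and 1.014 for vehicle and 0.9899 and 1.02 for A7. Values called scaled FPKM are these quotients. The 8952 genes with a mean FPKM of 1 or more over the 4 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with a mean-variance trend) on log2(scaled FPKM + 1), two-sided, A7 minus vehicle, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate the change of genes with low values. The model left 2 residual degrees of freedom per gene and added 3.89 prior ones. An exact two-sided permutation test of 2 against 2 samples cannot give a p below 0.333, so none is used as a criterion. IKBKB had a mean FPKM of 0.390, under the minimum, and was fitted together with the 8952 genes as a planned test of 1 gene, with its unadjusted p. The genes to name and 24 gene lists were set by a rule written before the data were examined, and genes chosen later are marked as such. The rule names 7 genes of the study's question (IKBKB, CHUK, IKBKG, ESR1, RELA, NFKB1 and BRCA1), 12 genes in each direction whose groups did not overlap (those past the threshold by size of the fold change, filled up by the smallest unadjusted p), and up to 4 members with the smallest p of each gene list. Small RNAs and genes with a near-identical copy, found with blastn 2.17.0 against GENCODE 29 transcripts (identity of at least 95% over at least 50% of the transcript), were not named among the 12. Symbols that GENCODE 29 does not hold were not searched for copies.

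Of the 24 lists, the 21 with at least 5 tested members were tested with camera (limma) with a preset inter-gene correlation of 0.01, which compares a list with all other tested genes, and adjusted over the lists. Camera with a correlation estimated from the data and fry are given beside it. Libraries with the same mean expression and spread were simulated (20 simulations of 8952 genes). In each, 200 genes were changed, all with a mean log2(scaled FPKM + 1) above 2. The test recovered 35.8% of 2-fold, 94% of 4-fold and 99% of 8-fold changes, and 6.3% of the calls were unchanged genes. Recovery among genes with lower values, such as IKBKB, was not simulated. Lists of 29 independent genes shifted by about -0.33 log2 units were called in 100% of cases and unshifted ones in 1%. The real lists called below had estimated correlations of 0.27 (estrogen-induced), 0.43 (ribosomal proteins), 0.17 (oxidative phosphorylation) and -0.036 (S phase). The simulated rates therefore do not carry over to lists of correlated genes.

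Depth was read from the steps of low values. Over the same low genes, the FPKM worth of 1 fragment gave a depth, relative to vehicle replicate 1, of 0.975 for vehicle replicate 2, 1.845 for A7 replicate 1 and 1.37 for A7 replicate 2. With transcript lengths from GENCODE 29 this corresponds to roughly 2600000, 2400000, 4900000 and 3600000 fragments. An FPKM of 1 at the median length of 2506 bases is then 5.9 to 12.2 fragments, and fragments derived this way are estimates. Intervals on them cover counting error only, since PCR copies are not independent molecules. The alternatives tried were other pseudocounts (0.1 and 0.01), other filters (none, and a mean FPKM of 5 or more), FPKM without scaling, FPKM rescaled to TPM (the same sum in every library), quantile normalization, other variance models, a minimum of 2-fold, the replicate number as a block, and leaving out each library in turn.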

Results

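Gene expression was measured by RNA sequencing in LCC9 cells, an estrogen receptor alpha-positive breast cancer line that grows in the presence of tamoxifen, after 24 h with vehicle (2 libraries) or with A7 (2 libraries), a compound that the labels call a mimetic of the tumour suppressor BRCA1. The sample titles and the series title give A7 different catalogue numbers, so only its code name is used. The title of the series has the compound lower IKBKB, which encodes the kinase IKKB that activates NF-kB, through the estrogen receptor at its promoter. Summed FPKM were 1324082 and 1473540 in the vehicle libraries and 1189056 and 1192830 in the A7 libraries. Estimated depth was low, roughly 2600000 and 2400000 fragments with vehicle and 4900000 and 3600000 with A7. Between 8763 and 9102 genes per library had an FPKM of 1 or more. The median absolute log2 difference across genes was 0.224 between the vehicle replicates and 0.201 between the A7 replicates, and it lay between 0.192 and 0.257 for pairs from different groups. Among genes with a mean FPKM of 10 or more it was 0.183 and 0.176 within groups and 0.160 to 0.254 between them.

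IKBKB was listed at 0.657 and 0.443 scaled FPKM with vehicle and at 0.299 and 0.153 with A7. The means were 0.550 ± 0.151 and 0.226 ± 0.103 (SD, n = 2 each), 2.43-fold lower with A7, and the groups did not overlap. On log2(scaled FPKM + 1) the difference was -0.34 (SE 0.26, 95% interval -0.98 to 0.31), and the planned limma test of this gene gave an unadjusted p = 0.246, so it did not pass. The value rests on about 19 estimated fragments in all, 11 with vehicle and 8 with A7, and the ratio of A7 to vehicle per depth was 0.421 with a 95% counting interval of 0.147 to 1.15 (exact binomial p = 0.0605). This interval includes 1, so a change of IKBKB was not shown at this depth. ESR1, which encodes the estrogen receptor, averaged 4.53 ± 0.36 with vehicle and 5.28 ± 0.11 with A7 (log2 difference 0.18, SE 0.17, limma adjusted p = 0.861), and BRCA1 averaged 6.86 ± 0.09 and 6.40 ± 0.56 (limma adjusted p = 0.935), a direction that turns with FPKM rescaled to TPM.

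**Figure D1:**
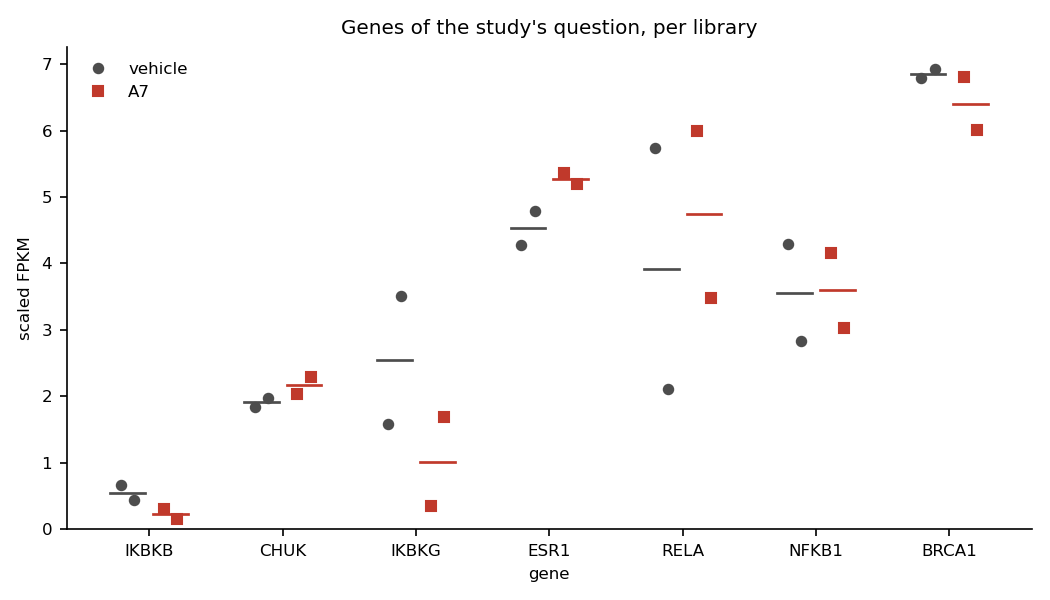
Scaled FPKM of the 7 genes of the study's question, with 1 point per library (circles, vehicle; squares, A7) and a line at each group's mean. IKBKB lies between 0.153 and 0.657 in all 4 libraries, and the groups of RELA, IKBKG, NFKB1 and BRCA1 overlap.

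The other parts of the NF-kB pathway and its target genes showed no common direction. CHUK, the sister kinase of IKBKB, averaged 1.91 ± 0.09 scaled FPKM with vehicle and 2.16 ± 0.18 with A7, and IKBKG, the regulatory subunit of the kinase complex, averaged 2.54 ± 1.36 and 1.02 ± 0.95 (limma adjusted p = 0.806). By estimated fragments, 26 with vehicle and 16 with A7, the ratio of IKBKG per depth was 0.356 with a 95% counting interval of 0.179 to 0.690 (exact binomial p = 0.00111), which leaves out the spread between replicates, and the groups overlapped. The search for near-identical copies covered only genes without overlap of the groups, so IKBKG was not searched and reads shared with a copy are not excluded. RELA and NFKB1, the subunits of the classical NF-kB dimer, had log2 differences of 0.29 (SE 0.41) and 0.02 (SE 0.25), both negative without vehicle replicate 2 and without A7 replicate 1, and that of NFKB1 also after quantile normalization. Of the 11 tested components 8 had a higher and 3 a lower mean with A7, with TAB2 at 0.41, TBK1 at 0.30 and the inhibitor NFKBIB at -0.40 on the log2 scale, and none passed over all genes or adjusted over the list alone. The list's median was 0.11 and its camera adjusted p 0.498, and the median turned negative without vehicle replicate 2 (-0.024) and without A7 replicate 1 (-0.095). Of the 10 tested NF-kB target genes 5 were higher and 5 lower. The transcription factor IRF1 averaged 1.46 with vehicle and 0.625 with A7, the stress-response gene IER3 13.4 and 23.4, the apoptosis inhibitor CFLAR 7.09 and 10.2, and the mitochondrial dismutase SOD2 9.94 and 6.72. The median of the target list was -0.05 and its camera adjusted p 0.834. This median turned positive with FPKM rescaled to TPM (0.13, but -0.042 relative to all genes), with no filter (0.019), without vehicle replicate 1 (0.14) and without A7 replicate 2 (0.16). Around the mean of the 4 libraries the list's medians were 0.035 and -0.12 with vehicle and 0.18 and -0.20 with A7. Replicates of both groups thus lay on opposite sides. Only these 10 of 38 listed target genes reached the FPKM minimum.

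Genes known to be induced by estrogen fell as a list with A7. Of 29 tested members 28 had a lower mean with A7, 16 of them without overlap of the groups, and the median log2 fold change was -0.33 (camera adjusted p = 1.84e-10). With an estimated correlation between genes the camera adjusted p = 0.503, and the directional fry test gave an adjusted p = 0.343. The call of a lower list thus rests on camera with the preset correlation. Camera with an estimated correlation also left the S-phase list uncalled, although that list's estimated correlation was -0.036. Camera with an estimated correlation also refers its statistic to the 2 residual degrees of freedom, whereas the preset correlation uses nearly as many as there are genes. For S phase the unadjusted camera p rose from 0.00272 to 0.0792 in this way. The lost calls thus reflect the few samples as well as any correlation between members, and do not decide whether the lists were lower. TFF1, a secreted trefoil peptide and classical estrogen target, was the most abundant member of the estrogen-induced list. It averaged 77830 ± 2970 scaled FPKM with vehicle and 35195 ± 164 with A7, 2.21-fold lower. The log2 difference was -1.14 (SE 0.12, limma adjusted p = 0.0857 over all genes). TFF1 made up 5.73% and 5.50% of summed FPKM with vehicle and 2.94% and 3.0% with A7. GREB1, a cofactor of the receptor, averaged 137 ± 7 and 83.6 ± 0.4, the scaffold protein gene PDZK1 167 ± 13 and 91.7 ± 11.9, and the growth factor gene AREG 17.8 ± 2.5 and 10.1 ± 0.5. PDZK1 shares near-identical sequence with its pseudogene PDZK1P1, which averaged 91.0 ± 7.8 and 47.8 ± 4.4, so the pair's reads could be split between them by the authors' counting. Adjusted over the list alone, 8 members passed, all lower, and 0 passed over all genes tested. Of the lists with a negative median it alone stayed below 0 with FPKM rescaled to TPM, which moved the median of all tested genes to 0.17. Relative to that shift, however, the other lists with a negative median also stayed negative, except luminal identity (0.043). The median of the estrogen-induced list was lower with A7 under every scaling tried, at -0.11 with FPKM rescaled to TPM and at -0.28 relative to the shift. The vehicle replicates differed in this list as well, with medians of 0.34 and 0.08 around the mean of the 4 libraries, against -0.11 and -0.28 for the A7 libraries, and without A7 replicate 2 the list's median was -0.20 (camera adjusted p = 2.64e-05).

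**Figure D2:**
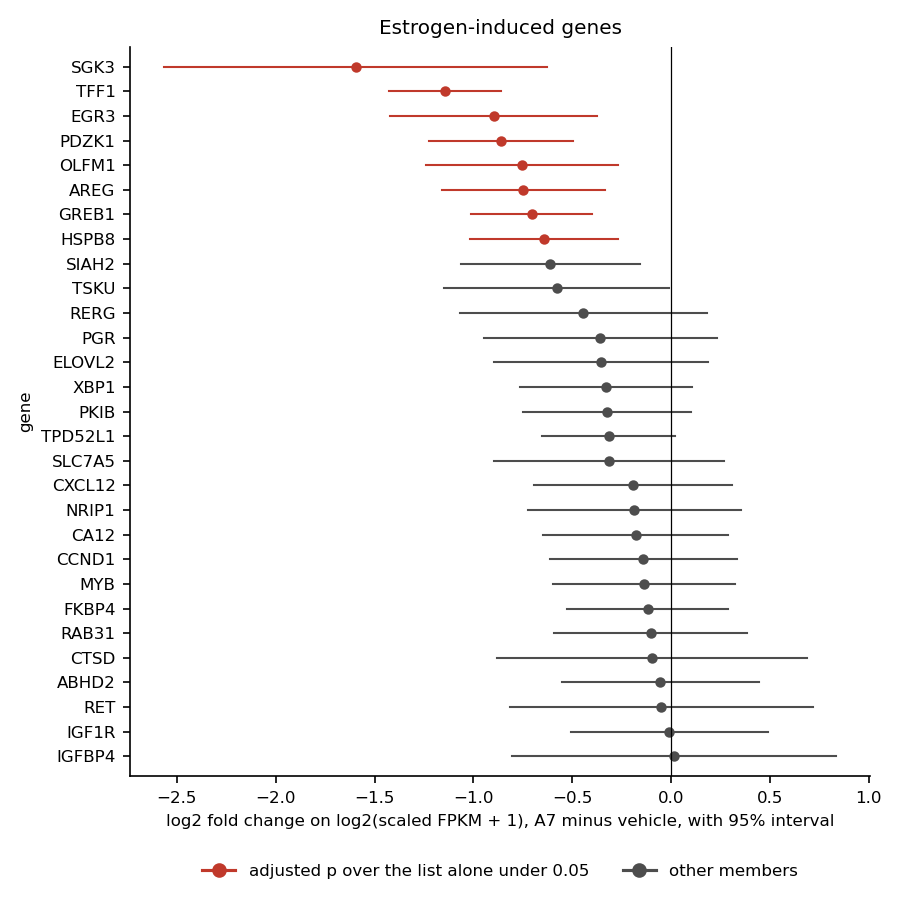
Log2 fold change of each of the 29 tested estrogen-induced genes, A7 minus vehicle, on log2(scaled FPKM + 1), with its 95% interval from limma; red marks the 8 genes with an adjusted p over the list alone under 0.05. 28 points lie below 0, and TFF1 lies at -1.14.

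Genes of luminal identity did not move together. Of 17 tested members 8 had a higher and 9 a lower mean, with a median near 0 (-0.0025) and a camera adjusted p of 0.599. The median turned positive with FPKM rescaled to TPM, after quantile normalization, without vehicle replicate 1 and without A7 replicate 2. Around the mean of the 4 libraries the list's medians were 0.020 and -0.024 with vehicle and 0.085 and -0.16 with A7, so the A7 replicates differed most. The transcription factors FOXA1, at 16.8 ± 3.1 and 22.7 ± 2.7 scaled FPKM, and GATA3, at 135 ± 4 and 165 ± 19, had higher means with A7, whereas TFAP2C averaged 49.2 ± 4.8 and 39.7 ± 4.4. TFF3, a trefoil peptide like TFF1, averaged 44.8 ± 10.8 with vehicle and 24.8 ± 8.5 with A7. None of these passed the limma test over all genes or adjusted over the list alone.

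Over all 8952 tested genes, 1 was higher and 1 lower with A7 at a limma adjusted p under 0.05. The small nucleolar RNA SNORD10 was listed at 0 in both vehicle libraries and at 38.0 and 95.5 scaled FPKM with A7 (adjusted p = 0.0365), and its sequence lies within transcripts of EIF4A1. It lies outside the naming rule and was chosen after its values were seen. HIST2H2BA was listed at 0 in both A7 libraries and at 7.89 and 10.1 with vehicle (adjusted p = 0.0365). It has near-identical copies among histone genes and is named as a member of the histone list, which was filled by symbol alone. At an unadjusted p under 0.05 there were 198 higher and 318 lower genes, 516 in all where 448 are expected by chance. The split by replicate number gave 637, and the split of crossed numbers (vehicle replicate 1 with A7 replicate 2) gave 207. Each of these other splits also gave 1 gene at a limma adjusted p under 0.05. With FPKM rescaled to TPM, which moved the median of all genes to 0.17, A7 against vehicle gave 716 higher and 96 lower genes at an unadjusted p under 0.05. After quantile normalization there were 209 and 263, so the balance of directions depends on the scaling. Groups did not overlap in 36.9% of the genes, where chance gives 33.3%, and 111 higher and 113 lower genes had both no overlap and at least a 2-fold difference. With FPKM rescaled to TPM or after quantile normalization, 1 was higher and 2 were lower. With no filter on low values or with the replicate number as a block 0 were higher and 0 lower, with a pseudocount of 0.1 or 0.01 0 were lower, and without the variance trend 0 were higher. The limma call of SNORD10 held under 8 of 14 alternatives and that of HIST2H2BA under 5 of 13. The counts depended on single libraries, with 0 higher and 0 lower without A7 replicate 1, 10 and 3 without A7 replicate 2, 1 and 6 without vehicle replicate 1, and 2 and 7 without vehicle replicate 2.

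Among the other genes named by the rule, none passed at an adjusted p under 0.05. Lower with A7 in both libraries were the cytokine gene IL20, at 119 ± 14 and 54.6 ± 1.5 scaled FPKM, the calcium-binding protein gene S100P, at 20.5 and 19.5 against 7.95 and 6.02 in the A7 libraries, the small GTPase gene RRAS, at 3.26 ± 0.05 and 0.978 ± 0.145, FITM2, which acts in lipid storage, at 6.91 ± 0.54 and 2.64 ± 0.71, and L3HYPDH, at 7.48 ± 0.99 and 3.36 ± 0.51. HIST1H4I, HIST1H3I, TMEM238 and KRTDAP were listed at 0 in both A7 libraries and at 1.71 to 5.97 in the vehicle libraries. Higher in both A7 libraries were ID2, an inhibitor of helix-loop-helix transcription factors, at 259 ± 1 and 387 ± 4, the metallothionein MT1F, at 44.5 ± 2.1 and 70.2 ± 0.9, the chemokine receptor gene CXCR7, at 48.1 ± 4.5 and 75.6 ± 3.4, RBL2, a pocket protein of the retinoblastoma family, at 3.35 ± 0.35 and 7.24 ± 0.33, and LYPD3, at 2.24 ± 0.22 and 5.93 ± 1.09. LINC00173 averaged 0.452 and 3.13, and UPK3BL 29.1 and 53.3. LOC440311 averaged 0.225 and 1.99. The genes HP07349 and LOC100129480 were listed at 0 with vehicle and at 5.07 and 2.09, and 2.85 and 1.34, in the A7 libraries. DYX1C1 and the read-through transcript C17orf61-PLSCR3 stood at nearly 0 with vehicle and averaged 1.99 and 2.55 with A7. Their counterparts, added after their values were seen, went the other way. The read-through transcript DYX1C1-CCPG1 averaged 2.48 with vehicle and 0.483 with A7, and PLSCR3 itself 5.00 and 0.847. The split of reads within each of these overlapping pairs is therefore uncertain.

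DNA replication and S-phase genes fell as a list, whereas single members did not pass. Of 25 tested members 19 had a lower mean with A7, and the median log2 fold change was -0.18 (camera adjusted p = 0.0143), a sign that flips to 0.0019 with FPKM rescaled to TPM (-0.17 relative to all genes). With an estimated correlation the adjusted p = 0.503, and leaving out vehicle replicate 1, vehicle replicate 2 or A7 replicate 2 ended the call (adjusted p of 0.056, 0.0715 and 0.0969). GINS2, a subunit of the replicative helicase, averaged 163 ± 11 scaled FPKM with vehicle and 111 ± 10 with A7. The helicase subunit MCM7 averaged 474 ± 46 and 381 ± 45, GINS1 87.2 ± 15.6 and 68.0 ± 1.3, and MCM5 4.41 ± 0.12 and 3.35 ± 0.25. No member passed adjusted over the list alone. The 27 mitosis genes had a median of -0.10 (camera adjusted p = 0.190) that turned to 0.115 with TPM (-0.060 relative to all genes). The cyclin CCNB1 averaged 149 ± 25 and 109 ± 8, and the cyclin CCNA2 6.49 ± 0.58 and 8.77 ± 0.42. The 23 homologous recombination and Fanconi genes had a median of -0.12 (camera adjusted p = 0.148) that turned to 0.0465 with TPM (-0.13 relative to all genes). RBBP8, which acts in DNA end resection, averaged 39.9 ± 9.9 and 28.3 ± 0.3, and the checkpoint kinase gene CHEK1 8.67 ± 1.87 and 6.61 ± 0.62. Camera called the latter list without vehicle replicate 1.

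Replication-dependent histone genes spread widely in both directions. Of 57 tested members 35 had a lower and 22 a higher mean with A7, with a median of -0.12 and quartiles of -1.14 and 0.29 (camera adjusted p = 0.0567). The median turned positive with FPKM rescaled to TPM (-0.064 relative to all genes) and after quantile normalization. Camera called it under 6 of the 12 alternatives that enter this test, with no filter, unscaled FPKM or TPM, or without vehicle replicate 1, A7 replicate 1 or A7 replicate 2. Adjusted over the list alone 5 passed, all lower, and 1 of them, HIST2H2BA, over all genes. HIST1H2AJ averaged 43.5 ± 3.9 and 12.1 ± 1.7 scaled FPKM, and HIST1H2AI 33.6 ± 6.8 and 6.98 ± 1.00, but this pair is near-identical in sequence and shares reads. The mixed fry test, which asks whether members move in either direction, gave an adjusted p = 0.0341 for this list and for the estrogen-induced and apoptosis lists.

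Ribosomal protein genes and nuclear genes of oxidative phosphorylation were slightly lower with A7 as lists. Of 83 tested ribosomal protein genes 77 had a lower mean, with a median of -0.17 (camera adjusted p = 1.5e-10), and of 70 respiratory chain genes 56 had a lower mean, with a median of -0.15 (camera adjusted p = 4.69e-05), but these signs flip to 0.050 and 0.072 with FPKM rescaled to TPM (-0.12 and -0.10 relative to all genes) and to 0.0070 and 0.00047 after quantile normalization. With an estimated correlation the adjusted p = 0.503 for both lists, and without vehicle replicate 2 the respiratory chain list no longer passed (median -0.068, adjusted p = 0.0715). Without A7 replicate 2 the medians were -0.088 for ribosomal proteins (adjusted p = 0.0162) and -0.13 for the respiratory chain (adjusted p = 0.0218). RPS7 averaged 2487 ± 146 and 1809 ± 105 scaled FPKM, RPS16 2710 ± 246 and 2013 ± 135, and RPL27 4330 ± 210 and 3266 ± 325. ATP5G1, a subunit of the ATP synthase, averaged 575 ± 36 and 430 ± 2, whereas COX5A, of cytochrome c oxidase, averaged 19.0 ± 0.9 and 29.3 ± 7.4. No member of either list passed, over all genes or adjusted over the list alone. Abundant genes outside both lists moved alike, since 93 of 104 such genes with a mean FPKM of 1000 or more had lower means with A7 (median -0.20), and 1739 genes with a mean of 1 to 2 had a median of 0.075. The tables hold no symbol of the list of genes of the mitochondrial genome.

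**Figure D3:**
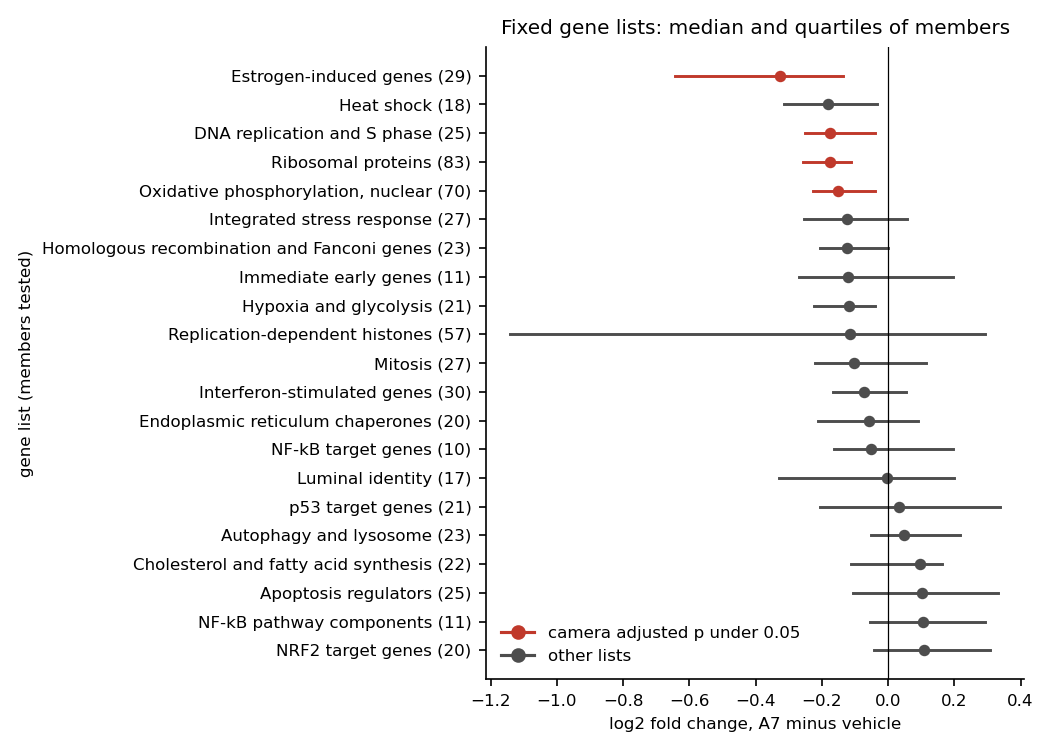
Median (point) and quartiles (line) of the log2 fold changes of tested members of each of 21 fixed gene lists, A7 minus vehicle, with the number of tested members in brackets; red marks a camera adjusted p under 0.05. Estrogen-induced genes lie lowest, at a median of -0.33. The red medians of the ribosomal, oxidative phosphorylation and S-phase lists turn positive with FPKM rescaled to TPM. Relative to all genes under that scaling they stay negative, at -0.12, -0.10 and -0.17.

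Stress and metabolic lists did not pass the planned camera test, but 3 of them passed under some alternatives. FPKM rescaled to TPM moved the median of all tested genes to 0.17. With it the medians turned to 0.033 for heat shock, 0.081 for the integrated stress response, 0.15 for endoplasmic reticulum chaperones and 0.085 for hypoxia and glycolysis. Relative to all genes these 4 medians stayed negative, at -0.14, -0.094, -0.023 and -0.090. Without vehicle replicate 1 the median of cholesterol and fatty acid synthesis turned to -0.016. Heat shock genes came closest, with 15 of 18 members lower and a median of -0.18 (adjusted p = 0.0534), and passed under 5 of the 12 alternatives that enter this test, with a pseudocount of 0.1 or 0.01, unscaled FPKM, the replicate block, and without A7 replicate 2. The NRF2 and cholesterol lists passed after quantile normalization. The chaperone genes HSPA8, at 1793 ± 259 and 1094 ± 267 scaled FPKM, and HSPE1, at 1213 ± 165 and 945 ± 24, had lower means with A7, while BAG3 averaged 16.8 ± 1.5 and 23.5 ± 2.3. Integrated stress response genes had a median of -0.13 (27 tested, adjusted p = 0.148), with the serine synthesis gene PSPH at 20.7 and 16.3, and endoplasmic reticulum chaperones a median of -0.06 (20 tested, adjusted p = 0.392), with SDF2L1 at 7.74 and 13.4. NRF2 target genes had a median of 0.11 (20 tested, adjusted p = 0.148), with NQO1 at 233 ± 28 and 290 ± 60. Hypoxia and glycolysis genes had a median of -0.12 (21 tested, adjusted p = 0.148), with lactate dehydrogenase A (LDHA) at 727 ± 81 and 539 ± 35, and ALDOC at 19.9 ± 1.7 and 13.5 ± 1.6. Cholesterol and fatty acid synthesis genes had a median of 0.10 (22 tested, adjusted p = 0.239), and INSIG1, a sterol-responsive regulator of the pathway, averaged 8.84 ± 0.92 and 14.7 ± 0.9. No member of these lists passed over all genes or adjusted over the list alone.

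Apoptosis regulators had more members with higher than with lower means with A7 (16 and 9 of 25), a median of 0.10 and a camera adjusted p of 0.0685. Camera called this list and the autophagy list when a mean FPKM of 5 or more was required. BAD, which promotes cell death, averaged 0.868 ± 0.010 and 2.33 ± 0.02 scaled FPKM, and MCL1, which opposes it, 11.2 ± 0.7 and 16.6 ± 0.7. Among 21 p53 target genes 12 had a higher mean (median 0.03, adjusted p = 0.355), and the stress cytokine gene GDF15 stood at 2.25 and 0.761 with vehicle and at 4.85 and 4.01 with A7. Interferon-stimulated genes had a median of -0.07 (30 tested, adjusted p = 0.229), with the transcription factor gene IRF7 at 3.87 ± 0.53 and 1.66 ± 0.25. Immediate early genes had a median of -0.12 (11 tested, adjusted p = 0.473), with EGR3, also an estrogen-induced gene, at 2.47 ± 0.11 and 0.866 ± 0.163, and EGR1 at 13.9 ± 0.8 and 17.0 ± 0.1. Autophagy and lysosome genes had a median of 0.05 (23 tested, adjusted p = 0.174), with the sialidase gene NEU1 at 12.1 ± 2.0 and 17.6 ± 2.4. With FPKM rescaled to TPM the medians turned to 0.15 for interferon-stimulated and 0.027 for immediate early genes (-0.027 and -0.15 relative to all genes). Interferon-stimulated genes also had 0.037 after quantile normalization. Immediate early genes had 0.12 with no filter and 0.041 without vehicle replicate 1. The median of p53 target genes turned to -0.0655 without vehicle replicate 1. None of these genes passed over all genes or adjusted over its own list alone, except EGR3 within the estrogen-induced list.

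Markers of other cell types were low, but several stood higher in A7 replicate 1. Of 16 basal and mesenchymal markers 11 were under 1 scaled FPKM in every library, and of 19 fibroblast and immune markers 13 were. The extracellular matrix gene DCN was listed at 0 in both vehicle libraries, at 8.40 in A7 replicate 1 and at 0.230 in A7 replicate 2, and SPARC stood at 0.213 and 0.431 with vehicle and at 7.98 and 0.456 with A7. With 3 tested members each, the lists were not tested as lists. S100A4, a calcium-binding protein gene of mesenchymal cells, averaged 9.24 ± 1.43 and 15.4 ± 1.7 and passed adjusted over its list alone (adjusted p = 0.0285, 1 of 3), not over all genes, while VIM averaged 6.21 ± 0.04 and 7.60 ± 1.09. CD68 averaged 4.13 and 3.81, and HBA1 3.22 and 3.40. Without A7 replicate 1 the estrogen-induced list had a median of -0.39 and the ribosomal protein list one of -0.23, and without A7 replicate 2 these were -0.20 and -0.088.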

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

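Against 1 gene higher and 1 lower with A7, the counts were 0 and 0 with no filter on low values, 0 lower with a pseudocount of 0.1 or 0.01, 3 lower with a mean FPKM of 5 or more, 2 lower with FPKM rescaled to TPM and after quantile normalization, 2 and 5 with robust eBayes, and 0 higher without the variance trend. With the replicate number as a block they were 0 and 0, on fewer residual degrees of freedom. At an unadjusted limma p under 0.05 the block gave 288 higher and 574 lower genes, against 198 and 318 without it. A shared effect of the replicate number is therefore not excluded. Same-numbered libraries deviated together with a correlation of 0.0906 across genes. The labels tie them to no shared day or batch and 2 pairs are too few to tell, so they were not treated as pairs. Leaving out 1 library gave 0 to 10 higher and 0 to 7 lower genes, with a lone library assumed to vary like the other group. The cause was not tested, except that other filters change how many genes are tested. SNORD10 passed under 8 of 14 alternatives (adjusted p 0.00477 to 0.703), HIST2H2BA under 5 of 13 (0.00686 to 0.703) and TFF1 under 4 of 14 (0.0088 to 0.972). IKBKB was lower under all 9 alternatives that alter its log2 difference, from -1.29 to -0.23, and the filters, variance models and block leave that difference as it is. Both A7 values lay below both vehicle values, so another pseudocount or leaving out 1 library could hardly change the sign. The shared sign therefore adds little. Over all 14 alternatives the unadjusted p of IKBKB ran from 0.0595 to 0.840.

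Against 4 lists called, 5 were called with either other pseudocount, no filter, a mean FPKM of 5 or more and the block, 6 with unscaled FPKM, 4 after quantile normalization (2 of them not among the first 4), 2 with FPKM rescaled to TPM, 0 with an estimated correlation and 0 with fry. Leaving out 1 library gave 2 without vehicle replicate 2 and 5 otherwise. The 2 other variance models do not enter camera and add nothing to these counts. The estrogen-induced list was called under the other 12 gene-level alternatives, with medians from -0.43 to -0.11. With an estimated correlation and with fry the adjusted p values were 0.503 and 0.343 for it (median -0.325), 0.503 and 0.377 for ribosomal proteins (-0.174), 0.503 and 0.363 for oxidative phosphorylation (-0.15) and 0.503 and 0.154 for S phase (-0.176). With FPKM rescaled to TPM the medians were 0.0504 for ribosomal proteins, 0.0722 for oxidative phosphorylation and 0.00191 for S phase, since that scaling moved all genes. After quantile normalization they were 0.00702 for ribosomal proteins and 0.000469 for oxidative phosphorylation. The S-phase list had a median of -0.216 and an adjusted p of 0.0851 with a mean FPKM of 5 or more, where fewer genes were tested. With 1 library left out, medians ran from -0.174 to -0.131 for S phase, from -0.232 to -0.0679 for oxidative phosphorylation, from -0.233 to -0.0881 for ribosomal proteins and from -0.429 to -0.202 for estrogen-induced genes. For 121 named genes, 1615 comparisons with an alternative kept their side of the threshold, 14 lost the call and 10 gained one. In 12 of the 1615 the sign changed, none of them past the threshold, in CD68, EBP, BRCA1, HBA1, NFKB1, RELA and IER2, with TPM, quantile normalization or 1 library left out. No gene that passed changed sign.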

Other observations

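Several abundant noncoding RNAs are not part of any list, and the genes named here were chosen after their values were seen. The nuclear RNAs MALAT1 and NEAT1 averaged 2866 ± 97 and 10.6 ± 1.1 scaled FPKM with vehicle and 3695 ± 153 and 17.1 ± 2.4 with A7, higher in both A7 libraries, with limma adjusted p of 0.806 for both. The 20 SNAR genes, short noncoding RNAs of near-identical sequence, held 17.1% and 17.5% of summed FPKM with vehicle and 15.7% and 15.4% with A7. Genes listed at 0 in both vehicle libraries and above 0 in both A7 libraries numbered 423, and the reverse 93, in libraries whose estimated depth was higher with A7. Of these, 8 and 5 reached the FPKM minimum. SERF1A and SERF1B, which are copies of each other, averaged 45.1 and 124 with vehicle and 111 and 27.1 with A7, so the counting may have split their reads differently in the 2 groups.

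The test of mean expression on the estrogen-induced list was chosen only after the result was seen, and the other tests below were set before their results. The lower estrogen-induced list could reflect less receptor activity with A7, a hypothesis that has no test of its own here. The tables argue against 3 technical explanations as the whole cause. The median was -0.28 with a trend of transcript length and GC content removed and -0.31 with a trend of mean expression removed. Camera with the preset correlation still called the list after either removal. With an estimated correlation it did not call the list even before removal (adjusted p = 0.503). Among the 11 members with a mean FPKM of 10 or more, of which 10 were lower, the median was -0.61, so genes with few reads do not hold the fall. Differences between libraries unrelated to A7 stay open, because the 4 libraries allow only 3 splits into 2 and 2, too few for a share under 0.05. In 1 of the 3 splits, the real one, the median was as large as -0.33 in size, and the highest other was 0.22, in the split by replicate number, where camera also called the list (adjusted p = 0.00972), along with luminal identity and NF-kB target genes.

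The lower ribosomal protein and respiratory chain lists are a different case. In the split of crossed numbers, which is unrelated to A7, camera called 1 list, that of ribosomal proteins. Over their 153 members the median of -0.15 became 0.021 once a smooth trend of mean expression, fitted on genes outside both lists, was removed, and camera no longer called either list, so these lists may only follow a trend shared by other abundant genes. Between replicates the trend was uneven. Genes with a mean FPKM of 1000 or more had a median difference of -0.15 between the vehicle replicates and 0.037 between the A7 replicates, those of 100 to 1000 -0.13 and -0.086, and those of 1 to 2 0.064 and 0.071. Fold changes did follow transcript length. The median log2 fold change was -0.109 for genes under 1 kb and 0.0733 for those over 4 kb. Between the vehicle replicates these medians were -0.0469 and -0.00265. Transcript length and GC content do not account for all of the fall of the pooled members. After removal of both trends the median was -0.12 in the 139 members with a known length, with -0.139 for ribosomal proteins and only -0.0805 for the respiratory chain. Nor does 1 library standing apart account for the pooled fall, with a median of -0.11 or lower without each library in turn. The respiratory chain list alone, however, had -0.068 without vehicle replicate 2, and the ribosomal list -0.088 without A7 replicate 2.

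For IKBKB, counting noise stays open as an explanation of the lower values. The ratio of estimated fragments per depth was 0.421, far from 1, but its 95% interval of 0.147 to 1.15 includes 1, and 19 fragments in all are too few to decide. A lower level with A7, as the series title has it, could fit the same values and was not tested apart from this.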
